A study of Chelon labrosus with 68 samples.

How the data were processed

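Transcripts of the thicklip grey mullet were measured on 68 Agilent 1-colour arrays, 38 of a field version (5 slides) and 30 of an exposure version (4 slides). Groups were taken from the labels: 8 field groups and 5 exposure groups of 6. Male liver replicate 5 of Arriluze is male by its title and description but female by its sex characteristic, and it was kept as male. The design text calls the 5 female liver samples of Ondarroa gonad, while their tissue characteristic and source name say liver, and they were kept as liver. Per the labels' protocols, total RNA was amplified from an oligo-dT primer and labelled with Cy3. The labels say that 1 female liver sample was labelled a second time as a control, and 1 array of it was used here. Which control belongs to which exposure is not given in the sources used here, so cadmium was set against seawater and benzo(a)pyrene and nonylphenol against acetone. The arrays of the 2 versions were scaled and tested separately.

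Per the file headers, the deposited scanner files hold spot intensity from Agilent Feature Extraction 9.5.3.1, background-subtracted and detrended within each array, with dim spots replaced by a small positive value. The authors also deposited tables of log2 values. Set against the scanner intensities, the field table is quantile normalized over the 38 arrays, and the exposure table is quantile normalized with the median of the 6 seawater controls taken from each probe. These tables entered only as an alternative. Gene names are those of the array design as deposited, written here with spaces and without species prefixes, and they can be old. The table of gene names supplied with the data was not used here, no genome was used, and probes were not mapped.

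From the scanner files, control spots and spots marked as non-uniform or population outliers were left out (34 to 79 spots on a field array and 32 to 112 on an exposure array). The processed intensity was turned to log2, repeat spots of a probe were averaged, and the 75th percentile over all probes of the array was subtracted. That percentile was an intensity of 747 to 3277 on the field arrays and 1864 to 4322 on the exposure arrays, and 0 probes were saturated. Repeat spots had a mean SD of 0.221 on the field version and 0.233 on the exposure version (log2). A probe was tested where at least 50% of its spots were well above background in at least 50% of the arrays of at least 1 group of the fit. Different probes of a gene were kept apart, and the text says where few of them passed.

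Tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05); labels were read with jsonlite 2.0.0. The 4 female Ondarroa tissues shared 1 fit, as did the 4 field liver groups, the 2 gonad groups, the liver and gonad groups of the interaction, and the 5 exposure groups. A tissue-enriched probe had to be higher than in each of the other 3 tissues, with an adjusted p under 0.05 in all 3 contrasts. Gene lists were matched on gene names and tested with limma's camera with an estimated correlation where at least 5 probes were tested, and with a preset correlation of 0.01 and with fry as alternatives. Most genes carried several probes, so list counts are of probes and cover far fewer genes. Heat shock, for example, held 12 probes of HSC70, HSP70 and HSP90. The preset correlation takes such probes as near independent, so its p-values overstate the evidence. Of the 22 lists, those for mitochondrial energy and for ovary, testis, gill and muscle markers held 0 probes, and the 5 probes of the steroidogenesis list were not tested in any liver or gonad comparison. Lists of mitochondrially encoded transcripts and of ribosomal RNA were added after the data were seen.

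The text names genes by this rule: per comparison, with 1 probe per gene (the lowest p), the 10 largest positive and 10 largest negative differences past the threshold, 8 genes per tissue, up to 4 genes per list, and in each liver or gonad comparison vitellogenin, choriogenin, oestrogen receptor, aromatase, CYP1A, metallothionein, HSP70, glutathione S-transferase, catalase and superoxide dismutase. Where fewer than 5 genes passed, the 5 smallest p-values are given. Not every such gene is printed. Groups, designs, lists, the naming rule and most alternatives were chosen before the data were examined.

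The tests were tested on simulated data drawn around the real probes. The simulated noise was independent between probes, with no shift of whole arrays and no slide effect, so the shares below do not cover such effects. For the site comparison (413 probes) 55% of probes changed by 1 log2 unit and 84.5% of those changed by 2 were found, with 4.99% false calls. For the gonads (401 probes) the shares were 50.2% and 88.2%, for cadmium (481 probes) 73.2% and 93%, for intersex liver (413 probes) 36.8% and 74.2%, and for males (413 probes) 57% and 85%. Alternatives changed the scaling, background correction, filter, spot handling, variance model, control, samples in the fit, slide and replicate blocks, or left out each replicate in turn. Same-numbered samples deviated together from their group means, with every correlation above 0.1, between liver and brain (5 pairs, lowest 0.102), liver and gill (5, 0.196), brain and gill (6, 0.200) and seawater and acetone (3, 0.217). The numbers were thus taken to pair these groups, from the values alone, since the labels do not say it. For seawater and acetone this rests on 3 pairs picked from all exposure groups. Over the 43 same-numbered exposure pairs the mean correlation was 0.006 and 17 lay above 0.1. Such a pick can arise by selection, so a pairing of seawater and acetone is not shown. Most of these tissue pairs also shared a slide, and all shared a side of the rRNA split described below. Brain and gill samples of unlike number on the same side correlated at 0.171 on average, against 0.258 for equal numbers. Slide, split and number were thus not fully separated. Scan session was identical to slide and was not run separately.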

Results

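The thicklip grey mullet (Chelon labrosus) is an estuarine fish used to watch coastal pollution, and its transcripts were measured here on 2 versions of a custom 1-colour array built around toxicology genes. The field version was hybridised with 38 samples from 2 sites of the Basque coast. Ondarroa gave female liver (n = 5), female gonad (n = 6), female brain (n = 6), female gill (n = 6), intersex liver (n = 2) and intersex gonad (n = 2), and Arriluze gave female liver (n = 6) and male liver (n = 5). The 5 female liver samples of Ondarroa are called gonad in the design text but liver in their tissue and source labels, and were taken as liver. The exposure version was hybridised with 30 liver samples of immature fish kept in seawater alone or exposed to acetone, cadmium, benzo(a)pyrene or nonylphenol, with 6 samples in each of the 5 groups. The labels used here give no doses. The field version carried 626 probes for 156 genes and the exposure version 638 probes for 159 genes. Between 43.6% and 62.9% of the probes were well above background on a field array, and between 53.1% and 78.2% on an exposure array, and the number of arrays limits the precision of every value. The labels do not say that the samples of a group came from separate animals, so each p-value measures the spread between these samples, which may be technical. No 2 arrays held the same data: the highest share of spots with equal intensity was 3.37e-04 among the 703 field pairs and 3.83e-04 among the 435 exposure pairs. Values are log2 intensities relative to the 75th percentile of the array, and differences are on the log2 scale with their standard error (SE).

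The first question was which array genes mark each tissue of females from Ondarroa. The genes highest in liver included several of the liver marker list. Fibrinogen G, a chain of the clotting protein, stood at 6.64 ± 0.70 (SD, n = 5) in liver, at least 2157-fold above brain, where no array measured it well above background. FABP, a fatty acid binding protein, stood at 6.26 ± 0.41, at least 1662-fold above brain, and Beta-Fibrinogen at 6.49 ± 0.50, at least 1945-fold above gonad. TBTbp stood at 6.66 ± 0.52, a difference of 11.60 from brain, where 2 of 6 arrays measured it. Haptoglobin, which binds free haemoglobin in plasma, was at least 152-fold higher in liver than in brain, and Complement Bf/C2 at least 52.0-fold. Prothrombin exceeded brain by 7.86 (measured on 4 of 6 brain arrays), and a-2 macroglobulin exceeded gill by 8.07 (2 of 6 gill arrays). Each fold bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the lowest signal among probes well above background or the probe's own signal, whichever was higher. For tissues, no array of the other 3 measured such a probe, and the highest of their 3 such means was taken, so the bound holds against each of them.

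The genes highest in ovary included PCNA, p53, Cyclin H and BAX of the DNA damage and cell cycle list. NAD(P)H quinone dehydrogenase, which reduces quinones, stood at 8.25 ± 0.11 (SD, n = 6) in ovary and 1.28 ± 1.83 in brain, the next tissue, a difference of 6.97 (adjusted p = 6.1e-08). PCNA, the sliding clamp of DNA replication, stood at 1.76 ± 0.18 and exceeded gill by 3.79. The tumour suppressor p53 exceeded gill by 3.27, Cyclin H by 3.60 (measured on 5 of 6 gill arrays) and BAX, which promotes apoptosis, by 2.87 (1 of 6). PMP70, a peroxisomal membrane transporter, exceeded brain by 2.76 (3 of 6 brain arrays). In gill, CYP1Bb, a cytochrome P450 of the CYP1 family, was at least 6.69-fold above brain, and GPX2, a glutathione peroxidase, stood at 4.73 ± 0.49 against 1.54 ± 0.60 in liver. The stress gene Gadd45a exceeded liver by 2.33 in gill, and gelatinase was at least 2.59-fold above brain. In brain, seabream-type GnRH, a hormone that drives gonadotropin release, was at least 5.98-fold above gill and was measured on 5 of 6 brain arrays. The dopamine receptor (5 of 6 arrays) was at least 5.62-fold above its next tissue, chicken-II GnRH (4 of 6) at least 4.03-fold, and CYP19A2, an aromatase that turns androgens into oestrogens (4 of 6), at least 2.84-fold. Calmodulin, a calcium sensor, stood at 3.04 ± 0.89 in brain and exceeded its next tissue by 1.43.

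In all, 467 of 483 tested probes differed between the 4 tissues by limma's F-test. Counting probes higher in a tissue than in each of the other 3, liver held 104 (27 genes), ovary 113 (31 genes), gill 64 (18 genes) and brain 42 (13 genes). Scaling to the median of each array gave 178 ovary probes, scaling to the probes measured on all arrays gave 18 gill probes, and a filter that asked for signal on every array of a group gave 22 brain probes. With slide as a block the counts were 102, 111, 68 and 43 in the same order.

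**Figure D1:**
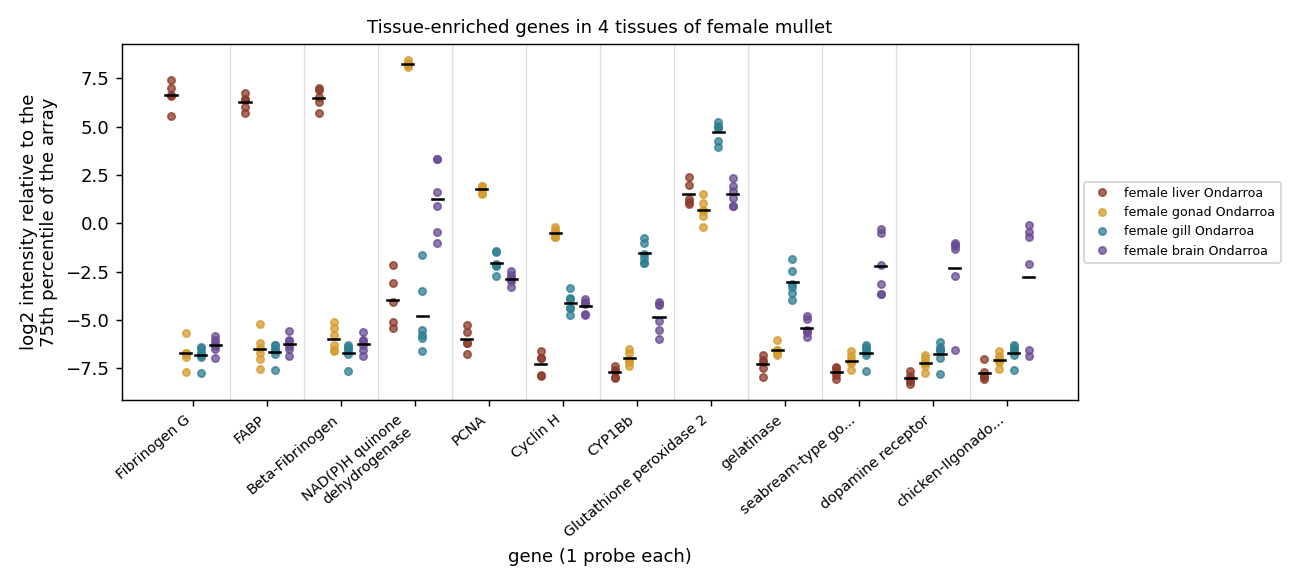
Tissue-enriched genes (1 probe each) in liver, gonad, gill and brain of female mullet, as log2 intensity relative to the 75th percentile of the array. Points are arrays and bars are group means; Fibrinogen G, for example, has a mean of 6.64 in liver.

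The comparison of female livers from Arriluze and Ondarroa asked how the hepatic profile differs between the 2 sites. CYP scc-24, a cytochrome P450, was higher in Arriluze by 3.41 (SE 0.60, adjusted p = 0.00159), at 2.19 ± 0.85 (SD, n = 6) against −1.22 ± 1.03 (SD, n = 5), in 6 of 6 samples above every Ondarroa sample. Heme oxigenase32, named for the enzyme that breaks down heme under oxidative stress, was higher by 3.05 (SE 0.59, adjusted p = 0.00271), with 3 of 5 Ondarroa arrays above background. The iron carrier Transferrin was higher by 1.26 (SE 0.31, adjusted p = 0.00808), above every Ondarroa sample in 5 of 6. Choriogenina L, an eggshell protein that the liver makes under oestrogen, fell by 4.20 in Arriluze (SE 0.84, adjusted p = 0.00271), measured on 1 of 6 Arriluze and 4 of 5 Ondarroa arrays, so its size rests on dim values. MxP, named for the interferon-induced Mx protein, differed by −3.02 (SE 0.60, adjusted p = 0.00271), measured on 2 of 6 Arriluze arrays, in 2 of its 4 probes.

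Among the antioxidant genes, 9 of 16 tested probes were lower in Arriluze (12 lower when adjusted over the list alone). These 16 probes cover only Catalase, Cu-Zn SOD, GPX2 and Peroxiredoxine. GPX2 fell by 1.49 (SE 0.26, adjusted p = 0.00159), below every Ondarroa value in 6 of 6 samples, and 1 of 4 Peroxiredoxine probes by 0.64 (SE 0.15, adjusted p = 0.00702). Catalase, which breaks down hydrogen peroxide, differed by 0.67 (SE 0.30, adjusted p = 0.117). Of 16 conjugation probes 8 were lower over all probes and 8 when adjusted over the list alone, GST (glutathione S-transferase) among them at −1.16 (SE 0.30, adjusted p = 0.00984). XDh fell by 1.49 (SE 0.24, adjusted p = 0.00159) in 6 of 6 samples. Gadd45a was not above background on any Arriluze array and was at least 2.26-fold lower there (adjusted p = 0.00159). The lipid receptor PPARg fell by 1.47 (SE 0.32, adjusted p = 0.00443) and Haptoglobin by 1.45 (SE 0.34, adjusted p = 0.00702), each in 6 of 6 samples. Of 14 tested probes of mitochondrially encoded transcripts, a list added after the data were seen, 10 were lower, as were 10 when adjusted over the list alone. Camera gave that list adjusted p = 0.653 with an estimated correlation. COX1 of that list differed by −0.93 (SE 0.21, adjusted p = 0.00501), ND4 by −0.88 (SE 0.21, adjusted p = 0.00702) and cytb by −0.78 (SE 0.22, adjusted p = 0.0213). The yolk and eggshell list had 4 lower of 12 (7 adjusted over the list alone), the nuclear receptors 4 lower of 8, the lipid list 4 lower of 21, DNA damage and cell cycle 4 lower of 16, efflux 1 lower of 5, and the aryl hydrocarbon receptor and CYP list 1 lower of 24 (0 adjusted over the list alone). Heat shock had 2 higher of 12, metal handling 4 higher and 4 lower of 12, immune and acute phase 8 lower of 25, liver markers 7 higher and 8 lower of 24, and ribosome and translation 0 of 8. The ribosomal RNA list, also added, had 0 of 10.

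No list passed with camera's estimated correlation, with or without slide as a block. Heat shock, for example, had an adjusted p of 3.19e-05 with the preset correlation and adjusted p = 0.809 with an estimated correlation. For the aryl hydrocarbon receptor list the median (−0.02) and the direction of the test (up) differed. The immune list (median 0.19, test up) and metal handling (median 0.02, test up) had means of the other sign, at −0.09 and −0.20. The yolk and nuclear receptor lists, which passed with the preset correlation, also had adjusted p = 0.809 with an estimated correlation. Several marker genes of pollution did not pass. VTG-B, a yolk precursor made under oestrogen, was not above background on any Arriluze array and on only 1 of 5 Ondarroa arrays. This gives at least 1.15-fold lower in Arriluze (adjusted p = 0.0703). VgC, another vitellogenin and not in the yolk list, was above background on 5 of 5 Ondarroa arrays (−2.33 ± 1.41, SD). Its differences in the liver comparisons are not given here. ERalpha, an oestrogen receptor, differed by −0.86 (SE 0.43, adjusted p = 0.148), CYP1A1, which oxidises aromatic hydrocarbons, by −0.15 (SE 0.43, adjusted p = 0.798), MT, a metallothionein that binds metals, by 0.10 (SE 0.31, adjusted p = 0.828) and HSP70, a chaperone, by 0.52 (SE 0.24, adjusted p = 0.127). Without Ondarroa replicate 1 ERalpha (−1.17) passed, as did VTG-B.

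In total 115 of 413 tested probes differed (37 genes), 21 higher and 94 lower in Arriluze, by limma. The split moved with the scaling. The median difference of all tested probes was −0.35 here, 0.01 with scaling to the probes measured on all arrays (57 higher, 18 lower), 0.14 with median centring (35 higher, 11 lower), −0.03 with quantile normalization (22 higher, 28 lower) and −0.03 in the authors' table (23 higher, 28 lower). Under every one of these scalings 22 probes kept their call and sign: 13 higher in 4 genes (CYP scc-24, Heme oxigenase32, HSC70 and Transferrin) and 9 lower in 5 genes (Choriogenina L, Gadd45a, GPX2, MxP and XDh). The mitochondrial COX1 kept its call only with scaling to the probes measured on all arrays, and ND4 and cytb lost theirs under each other scaling, though all 3 stayed negative. GST and Haptoglobin lost their calls under median centring and under scaling to the probes measured on all arrays. PPARg and Peroxiredoxine lost theirs under each other scaling. With slide as a block 57 probes passed (12 higher, 45 lower). Within the 4 slides that held both groups CYP scc-24 differed by 0.90 to 5.01, Choriogenina L by −7.49 to −1.77, GPX2 by −2.21 to −0.72 and XDh by −2.08 to −0.31. The field arrays also split into 2 sets of 19 by their 18S and 28S rRNA signal, with 4 called (0 higher, 4 lower) in the set of higher signal and 16 (8 higher, 8 lower) in the other.

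**Figure D2:**
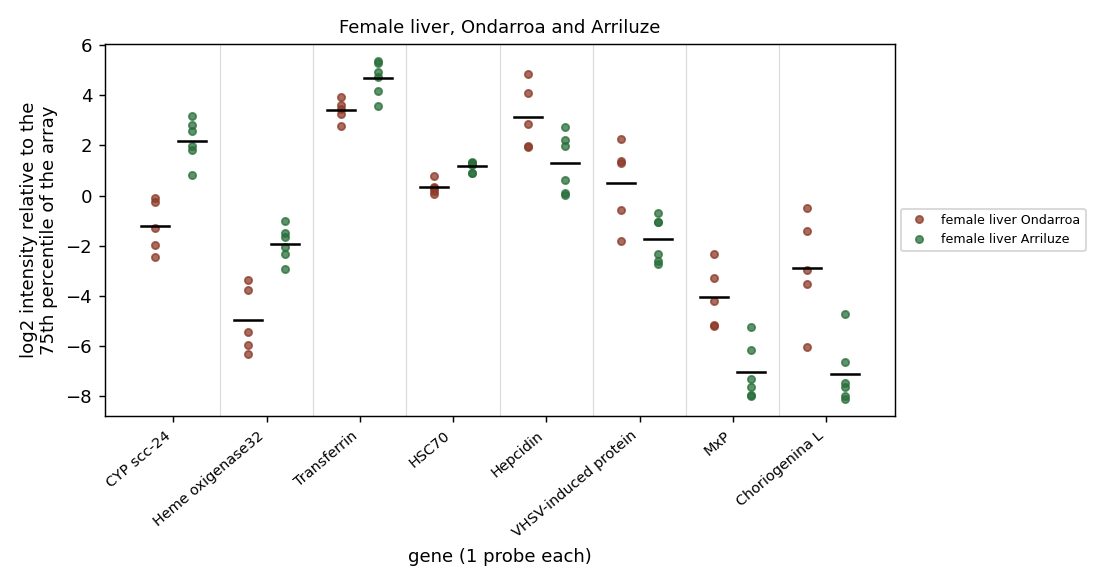
Genes of the liver comparison between females of Ondarroa and Arriluze (1 probe each), as log2 intensity relative to the 75th percentile of the array. Points are arrays and bars are group means; CYP scc-24 has means of 2.19 in Arriluze and −1.22 in Ondarroa.

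Male and female livers from Arriluze were compared to look for sex differences at 1 site. No gene passed: limma called 0 of 413 probes, with 28 under an unadjusted p of 0.05. The smallest p-values belonged to XDh at 1.18 in males relative to females (SE 0.24, adjusted p = 0.0626), the mitochondrial NDsub1 at 0.74 (SE 0.18, adjusted p = 0.0847), Gadd45a, not above background on any female array and on 2 of 5 male arrays, at least 1.28-fold higher (adjusted p = 0.208), CYP scc-24 at −1.94 (SE 0.60, adjusted p = 0.208) and MT at 0.80 (SE 0.30, adjusted p = 0.498). VTG-B was not above background on any of the 11 arrays, and Choriogenina L was measured on 2 of 5 male and 1 of 6 female arrays (difference 0.79, SE 0.91, adjusted p = 0.834). The VTG-B result does not cover VgC, the vitellogenin measured in Ondarroa livers, which is not given here. No list member passed over all probes; adjusted over the list alone, 2 DNA damage and 2 mitochondrially encoded probes did. The mitochondrial list had camera's adjusted p = 0.131 with an estimated correlation and 3.34e-07 with the preset one. Without female Arriluze replicate 1, 4 probes were called, XDh among them, a single fit over all field arrays called 2, and leaving out male replicate 5, whose sex labels disagree, gave 0. The median of all differences was 0.13 here and −0.27 with scaling to the probes measured on all arrays.

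Intersex fish carry ovarian and testicular tissue together, and here their livers and gonads were set against those of females from the same site. In liver (n = 2 against n = 5) limma called 0 of 413 probes, with 21 under an unadjusted p of 0.05. BHM differed by 2.93 (SE 0.97, adjusted p = 0.695), Transferrin by 1.35 (SE 0.43, adjusted p = 0.695), PolyU by −0.84 (SE 0.29, adjusted p = 0.720) and CYP4 by −1.0 (SE 0.36, adjusted p = 0.731). VTG-B was above background on 2 of 2 intersex and 1 of 5 female arrays, with a difference of 2.70 (SE 1.14, adjusted p = 0.787). No list member passed over all probes, and 4 metal handling probes did when adjusted over the list alone. Leaving out female Ondarroa liver replicate 5 gave 4 calls, as did leaving out intersex liver replicate 1.

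In gonad the difference covered most of the array. The mitochondrially encoded transcripts were higher in the intersex gonads: COX1, a subunit of cytochrome oxidase, stood at 5.36 ± 0.14 (SD, n = 2) against −0.92 ± 0.45 (SD, n = 6), a difference of 6.28 (SE 0.32, adjusted p = 6.3e-07), and cytb at 4.68 ± 0.05 against −1.64 ± 0.54, a difference of 6.31 (SE 0.37, adjusted p = 1.2e-06). All 14 tested probes of that list rose, but the list had camera's adjusted p = 0.155 with an estimated correlation and 1.06e-05 with the preset one. The oestrogen receptor ERalpha, not above background on any female array, was at least 14.4-fold higher (adjusted p = 6.1e-07), and ERb differed by 5.28 (SE 0.42, adjusted p = 5.7e-06). Ependymin rose by 6.47 (SE 0.70, adjusted p = 3.4e-05, measured on 2 of 6 female arrays) and ApoE, a lipid carrier, by 5.84 (SE 0.98, adjusted p = 5.1e-04). Among the lower genes, PCNA stood at −1.38 ± 0.21 against 1.83 ± 0.19, a difference of −3.21 (SE 0.19, adjusted p = 1.3e-06), and PEPCK, an enzyme of glucose synthesis, was at least 10.8-fold lower (adjusted p = 6.1e-07). Each of these differences was shown by both intersex samples against all 6 females. The ribosomal RNA moved with the group as well: 18S rRNA differed by 5.18 (SE 0.19, adjusted p = 2.0e-07) and 28S rRNA by 5.14 (SE 0.20, adjusted p = 2.2e-07).

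No list passed here with camera's estimated correlation. The list counts below are of probes, several to a gene, and so cover far fewer genes. With the 75th percentile scaling, all 8 nuclear receptor probes rose, PPARg by at least 12.6-fold and RXR by 3.13 (SE 0.31), and the list had adjusted p = 0.544 with an estimated correlation and 0.0116 with the preset one. Of 21 lipid probes 17 rose and 4 fell, FABP being at least 5.94-fold higher (list adjusted p = 0.544 with an estimated correlation). Of 21 immune probes 17 rose and 4 fell, and of 24 liver marker probes 20 rose and 4 fell, with Prothrombin at least 8.85-fold higher and Hepcidin at −2.07 (SE 0.52, adjusted p = 0.00496). Both of these lists had adjusted p = 0.544 with an estimated correlation. Of 32 DNA damage and cell cycle probes 24 fell and 4 rose: p53 fell by 2.18 (SE 0.15), Cyclin H by 2.44 (SE 0.19), and BAX was at least 4.60-fold lower. That list had adjusted p = 0.544 with an estimated correlation and 1.7e-04 with the preset one. All 12 heat shock probes fell, but they cover only HSC70, HSP70 and HSP90. HSP90 differed by −1.62 (SE 0.22) and HSC70 by −1.54 (SE 0.33), and the list had adjusted p = 0.544 with an estimated correlation. Of 16 antioxidant probes 12 fell and 4 rose: Catalase fell by 2.84 (SE 0.45) and Cu-Zn SOD by 2.24 (SE 0.16), with list adjusted p = 0.574 with an estimated correlation. MT fell by 2.12 (SE 0.22), within a metal handling list of 8 lower and 4 higher of 12. PCNA, p53, Cyclin H, BAX, HSP90, Cu-Zn SOD, MT, PEPCK and 1 Catalase probe were also ovary-enriched, a call that used these same female gonad arrays. ERb was ovary-enriched too but rose, while HSC70 and HSP70 fell without being ovary-enriched. A change of these lists thus cannot be told apart from a different makeup of the gonad. The aryl hydrocarbon receptor list had 9 higher and 1 lower of 15, conjugation 3 higher and 8 lower of 15, ribosome 4 higher of 8, efflux 0 of 5, and ribosomal RNA 10 higher of 10 (list adjusted p = 0.155 with an estimated correlation). The marker lists of 1 gene each, Trypsin for pancreas (4 of 4 probes higher), Calmodulin for brain (3 higher) and Haptoglobin for blood (4 higher), were too small for a list test. Haptoglobin entered the blood list through a match within its name and is also in the liver marker list, so its rise does not mark blood. CYP1A1 differed by 1.21 (SE 1.09, adjusted p = 0.327) and by 1.79 without female gonad replicate 4, when it passed.

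Of 401 tested probes 340 differed (94 genes), 190 higher and 150 lower, by limma. The median difference of all tested probes was 0.51 here, −0.44 with scaling to the probes measured on all arrays (140 higher, 191 lower), −1.11 with median centring (119 higher, 215 lower), −0.22 with quantile normalization (157 higher, 159 lower) and −0.22 in the authors' table (156 higher, 159 lower). Under all of these scalings 265 of the 340 probes kept their call and sign, in 36 genes higher and 40 lower. The mitochondrial, oestrogen receptor, PPARg, RXR and FABP values stayed positive and those of the heat shock genes, PCNA, p53, Cu-Zn SOD, MT and Catalase negative, while Trypsin, Calmodulin and Beta-Fibrinogen turned negative under at least 1 scaling. Slide 2 alone held both groups (1 sample each); there COX1 differed by 6.67 and PCNA by −3.19, and 249 probes passed with slide as a block, a contrast that rests on these 2 arrays. All 6 female gonads belonged to the set of 19 field arrays with the lower rRNA signal and both intersex gonads to the set with the higher. A fit over all 38 field arrays with a term for the set called 307 probes. That term came from liver, brain and gill alone, so it cannot remove a set effect particular to gonad. HSP70 differed by −1.02 (SE 0.32, adjusted p = 0.0151) and lost its call with slide as a block and without intersex gonad replicate 1.

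The difference between intersex and female fish was itself unequal in gonad and liver. The interaction passed for 252 of 470 probes, 149 with a larger value in gonad and 103 with a smaller one, including probes not above background in a group. COX1 gave 6.30 (SE 0.44, adjusted p = 4.2e-07), cytb 6.11 (SE 0.53, adjusted p = 1.3e-06), ERb 5.17 (SE 0.69, adjusted p = 4.8e-05, measured on 4 of 6 female gonad and 4 of 5 female liver arrays), Catalase −2.70 (SE 0.69, adjusted p = 0.00460) and p53 −1.90 (SE 0.39, adjusted p = 9.9e-04, measured on 4 of 5 female liver arrays). All 14 mitochondrial probes were larger in gonad, where camera gave adjusted p = 0.0637 with an estimated correlation. HSP70 did not pass, at −0.46. The median of all tested probes was 0.43 here, −0.52 with scaling to the probes measured on all arrays, −1.19 with median centring and −0.34 with quantile normalization. The split was 118 larger and 171 smaller, 82 and 198, and 130 and 125 in the same order, and 131 and 126 in the authors' table, and 217 probes passed with slide as a block (134 and 83).

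**Figure D3:**
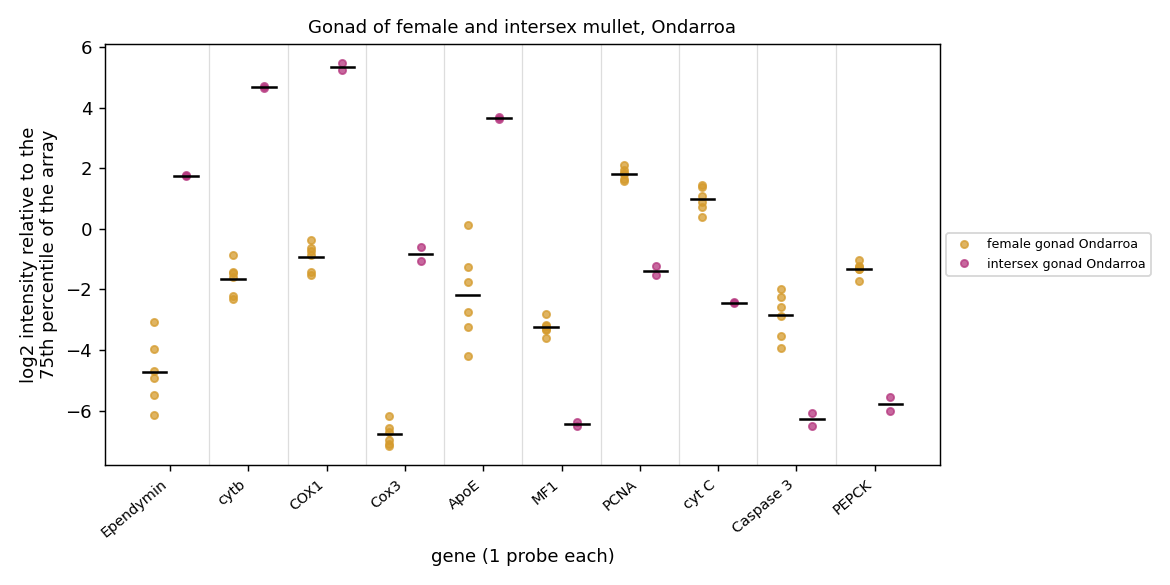
Genes of the gonad comparison (1 probe each) as log2 intensity relative to the 75th percentile of the array, in female (6 arrays) and intersex (2 arrays) mullet of Ondarroa. Points are arrays and bars are group means; COX1 has means of −0.92 and 5.36.

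**Figure D4:**
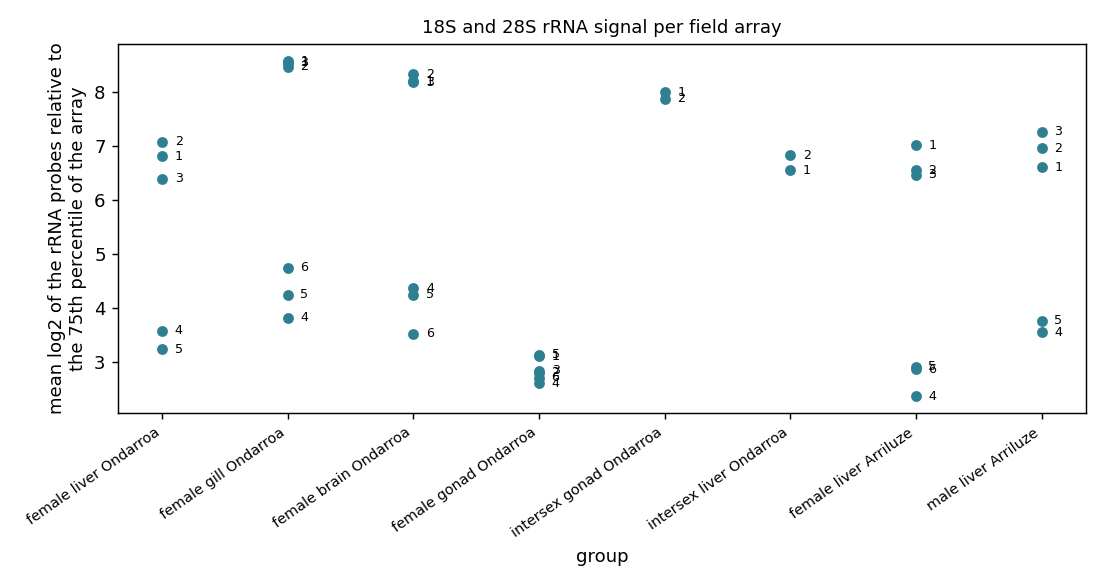
Mean log2 signal of the 18S and 28S rRNA probes per field array, relative to the 75th percentile of the array, with the replicate number beside each point. The 19 arrays of higher signal lie at or above 6.39 and the other 19 at or below 4.74, and all 6 female gonad arrays are among the latter.

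The exposures of immature fish asked how the liver responds to single pollutants. Acetone, taken here as the solvent control, was set against seawater first. Limma called 0 of 481 probes, with 18 under an unadjusted p of 0.05. Choriogenina L stood at −6.56 ± 1.69 (SD, n = 6) with acetone and −8.96 ± 1.08 (SD, n = 6) in seawater, a difference of 2.39 (SE 0.76, adjusted p = 0.992), measured on 5 of 6 and 1 of 6 arrays. Catalase differed by 0.58 (SE 0.24), L12 by −0.33 (SE 0.14), RXR by −0.31 (SE 0.14) and Fo by −0.29 (SE 0.12), each with adjusted p = 0.992. In the yolk and eggshell list 0 of 8 tested probes passed over all probes and 3 were higher when adjusted over the list alone. Camera gave that list adjusted p = 0.0673 with an estimated correlation, 1.23e-07 with the preset one, 0.0175 on the authors' table and 0.030 with quantile normalization, and 0.0297 without seawater replicate 3 and 0.0374 without acetone replicate 7. The median of all differences was −0.04 here and 0.08 with scaling to the probes measured on all arrays.

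Cadmium lowered 12 probes of 4 genes. COX1 stood at 1.90 ± 0.40 (SD, n = 6) with cadmium and 3.32 ± 0.61 (SD, n = 6) in seawater, a difference of −1.42 (SE 0.23, adjusted p = 4.8e-04), and 5 of 6 samples lay below every control. XDh differed by −1.09 (SE 0.24, adjusted p = 0.0139; 6 of 6 samples), ki-Ras, a GTPase of growth signalling, by −0.82 (SE 0.19, adjusted p = 0.0192; 5 of 6) and RXR, a partner of many nuclear receptors, by −0.57 (SE 0.14, adjusted p = 0.0284; 5 of 6). MT, the classic metal-binding protein, differed by 0.06 (SE 0.26, adjusted p = 0.891), HSP70 by 0.52 (SE 0.21, adjusted p = 0.164) and Cu-Zn SOD by −0.48 (SE 0.18, adjusted p = 0.127). Of the mitochondrially encoded probes 2 of 18 were lower (3 adjusted over the list alone), with camera's adjusted p = 0.291 at an estimated correlation. DNA damage had 4 lower of 30, nuclear receptors 2 of 16 (4 adjusted over the list alone), lipid 2 of 25 (4), antioxidant 0 of 16 (4 lower adjusted over the list alone), and heat shock and metal handling 0 of 12 each. Heat shock had an adjusted p of 1.49e-08 with the preset correlation and adjusted p = 0.478 with an estimated correlation, which was also the value of the nuclear receptor and metal handling lists.

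Scaling changed the cadmium result. The median difference of all 481 probes was −0.21 here and 0.09 with median centring, 0.05 with scaling to the probes measured on all arrays and −0.06 with quantile normalization, and 2 probes, both of COX1, kept their call under every scaling, while XDh, ki-Ras and RXR lost theirs under each of them. Within the 3 slides that held both groups COX1 differed by −1.65 to −0.71, XDh by −1.06 to −0.86, ki-Ras by −0.96 to −0.31 and RXR by −0.65 to −0.48, and 13 probes passed with slide as a block. Against acetone as the control 2 probes passed, both of COX1 (−1.31), and XDh (−0.90), ki-Ras (−0.51) and RXR (−0.26) did not. The count moved to 4 without seawater replicate 2, 2 without seawater replicate 4, 22 without seawater replicate 5 (5 higher, 17 lower), 50 without seawater replicate 6 (5 higher, 45 lower), 4 without seawater replicate 7, 4 without cadmium replicate 6 and 2 without cadmium replicate 9. In each of these fits COX1 passed; XDh lost its call without seawater replicate 4 and cadmium replicate 9, and ki-Ras and RXR without seawater replicates 2, 4 and 7 and cadmium replicates 6 and 9. Cu-Zn SOD passed without seawater replicate 6, at −0.58.

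Benzo(a)pyrene, an aromatic hydrocarbon that binds the aryl hydrocarbon receptor, lowered 10 probes of 4 genes relative to acetone. Catalase stood at −2.42 ± 0.35 (SD, n = 6) against −1.28 ± 0.51 (SD, n = 6), a difference of −1.13 (SE 0.24, adjusted p = 0.00889), below every acetone value in 6 of 6 samples. IGFI, the growth factor, differed by −0.80 (SE 0.20, adjusted p = 0.0241; 4 of 6 samples), cyclin G1 by −1.04 (SE 0.28, adjusted p = 0.0361; 1 of 4 probes, 4 of 6 samples) and RAG1 by −0.63 (SE 0.16, adjusted p = 0.0243; 1 of 3 probes, 5 of 6 samples). CYP1A1 differed by 0.01 (SE 0.19, adjusted p = 0.964) and Choriogenina L by −1.98 (SE 0.78, adjusted p = 0.132). In the antioxidant list 4 of 16 were lower (8 adjusted over the list alone) and in the lipid list, which also holds Catalase, 4 of 25 (10 adjusted over the list alone), both with camera's adjusted p = 0.635 at an estimated correlation. The aryl hydrocarbon receptor and CYP list had 0 of 27 (5 lower adjusted over the list alone) and adjusted p = 0.635 with an estimated correlation, and DNA damage 1 lower (8).

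No probe of the benzo(a)pyrene comparison passed under quantile normalization, median centring or normexp, 1 passed in the authors' table, and 0 passed with seawater as the control, where Catalase differed by −0.58, IGFI by −0.67, cyclin G1 by −0.71, RAG1 by −0.48 and Choriogenina L by 0.44. The median difference of all probes was −0.14 here and 0.08 with median centring. Within the 4 slides Catalase differed by −1.90 to −0.48, IGFI by −1.42 to −0.12, cyclin G1 by −2.14 to −0.13 and RAG1 by −0.95 to −0.15, and 13 probes passed with slide as a block. The count was 24 without acetone replicate 2, 4 without acetone replicate 4, 4 without acetone replicate 8, 5 without acetone replicate 9, and 18, 5, 20 and 17 without benzo(a)pyrene replicates 2, 3, 4 and 5. Catalase kept its call in each of these, and IGFI lost it without acetone replicates 4, 8 and 9 and benzo(a)pyrene replicate 3. Likewise cyclin G1 lost its call without acetone replicates 1, 4, 7, 8 and 9 and benzo(a)pyrene replicates 2, 3, 7 and 9, and RAG1 without acetone replicates 1, 4, 7 and 8 and benzo(a)pyrene replicate 9.

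Nonylphenol, an oestrogen-like surfactant product, gave 0 called probes of 481 by limma against acetone, with 62 under an unadjusted p of 0.05. Choriogenina L differed by −2.53 (SE 0.76), measured on 2 of 6 nonylphenol and 5 of 6 acetone arrays, BMP by −0.66 (SE 0.22), IGFI by −0.57 (SE 0.20), RAG1 by −0.49 (SE 0.16) and Pyruvate kinase by 0.56 (SE 0.18), each with adjusted p = 0.293. Against seawater, which could equally be the control by the labels, Choriogenina L differed by −0.13. The yolk and eggshell list had 4 probes lower when adjusted over the list alone and camera's adjusted p = 0.643. Without acetone replicate 7, 4 probes passed, Choriogenina L among them. The direct comparison of nonylphenol with benzo(a)pyrene gave 0 probes by limma and 28 under an unadjusted p of 0.05. N-acetyltransferase differed by 0.47 (SE 0.15, adjusted p = 0.776), and HSC70 by 0.68 (SE 0.25), Catalase by 0.58 (SE 0.24), eIF by 0.36 (SE 0.15) and CYP7 by 0.74 (SE 0.32), each with adjusted p = 0.851. CYP1A1 differed by −0.28 (SE 0.19, adjusted p = 0.872), and 4 conjugation probes were higher when adjusted over the list alone. The median of all differences was −0.09 here and 0.02 with quantile normalization against acetone, and 0.05 here and −0.10 with median centring against benzo(a)pyrene.

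**Figure D5:**
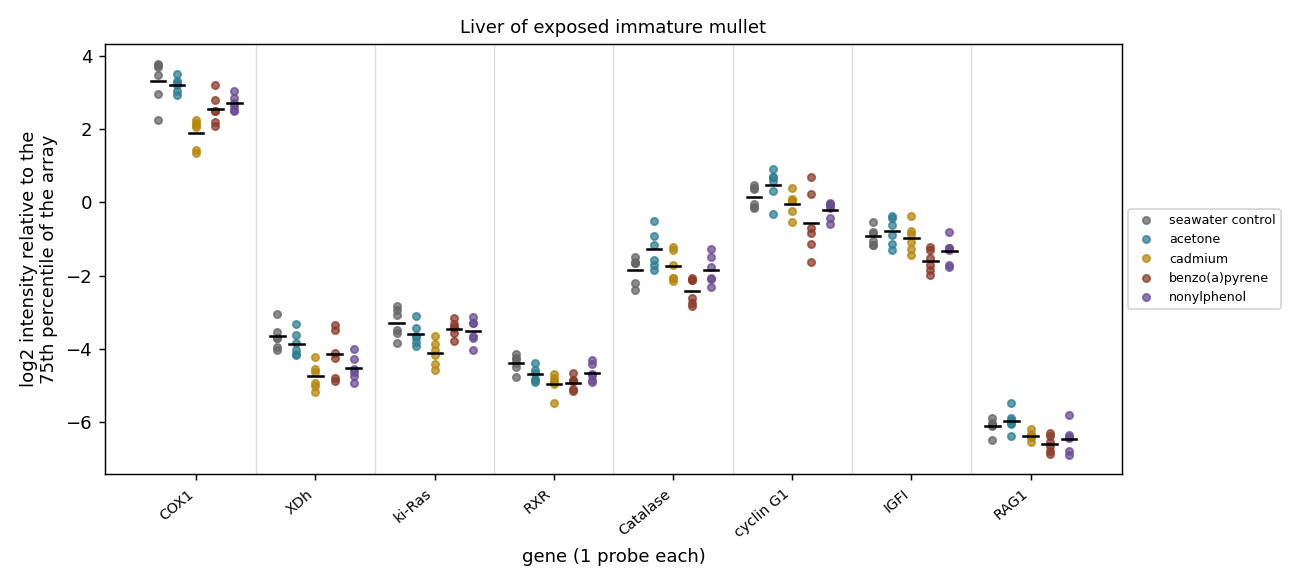
Liver genes of immature mullet (1 probe each) in seawater, acetone, cadmium, benzo(a)pyrene and nonylphenol, as log2 intensity relative to the 75th percentile of the array. Points are arrays (6 per group) and bars are group means; COX1 has means of 3.32 in seawater and 1.90 with cadmium.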

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

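The tests of the patterns weighed here were chosen after the results were seen, except the test for liver tissue and the other splits of the samples, which were planned before.

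A split of the field arrays by ribosomal RNA runs across the study's groups. The mean signal of the 10 probes for 18S and 28S rRNA was at least 6.39 on 19 arrays and at most 4.74 on the other 19, and in the 5 groups with arrays on both sides replicates 1 to 3 were on the higher side and later numbers on the lower. Slide could not separate the sets, since 5 of 5 slides held both; array brightness differed by −0.065 (log2, mean over groups) where the rRNA signal differed by 3.81; and tissue, site or sex cannot be the whole cause, since 5 of 8 groups held both. Of 500 probes 123 differed between the sets, from CYP1A1 at −1.65 to MHC II at 2.79 among those outside rRNA. A step that followed the replicate numbers, such as RNA extraction or amplification, may lie behind it, which was not tested, and no label names one.

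Most of the array differed between intersex and female gonad (340 of 401 probes), and these groups also lay on opposite sides of the rRNA split. A term for the split, fitted over all field arrays, left 89.4% of the 330 called probes outside rRNA with their call and sign. It took the median of the rRNA probes from 5.01 to 1.15, so the split may account for most of the rRNA difference. But neither gonad group held both sets, so the term came from liver, brain and gill alone. Most calls thus outlast a split effect of the size seen there, while one particular to gonad could not be removed and stays undecided. Slide as a block left 62.1% of the tested probes called, but only slide 2 held both groups, with 1 array of each, so the block cannot decide. Within slide 2 all 340 called probes kept the sign of the group difference, but the calls used these arrays, so this was close to fixed in advance. The intersex gonads, on slides 2 and 5, differed alike from the females on slides 1 to 4 for the genes first named above. For those genes this argues against slide as the whole cause. But they were chosen from the same arrays, with 1 array of each group within a slide. Liver tissue in the intersex gonad would place the 12 liver-enriched genes that rose there at 1 common distance below liver. The distance ranged over 14.3 (log2), and over 7.20 without ERalpha. But several of these genes, such as HGF at −4.81, lay near the lowest measured signal of the intersex gonad arrays (−4.99 and −4.51). For them the distance follows the level in liver, so the range was bound to be wide and cannot decide. A different makeup of the gonad in intersex fish stays open and was not tested. Several of the genes that fell were also ovary-enriched, as named above, though that call used the same female gonad arrays.

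Most called probes were lower in female liver of Arriluze than of Ondarroa. This imbalance moved with the scaling: with median centring 23.9% of the called probes were lower and with scaling to the probes measured on all arrays 24%. Each of these moves all probes of an array alike and so sets the balance, and the scaling and a shift of most probes between the sites cannot be told apart. With a term for the rRNA split 80.3% were lower, and 78.9% with slide as a block. But both groups were spread near evenly over the sets (3 higher and 3 lower in Arriluze, 3 and 2 in Ondarroa), and 4 slides held both. Split and slide thus had little room to shift the comparison and a term for either little to remove, so these shares decide little. Within the sets 4 of 4 called probes were lower at the higher rRNA signal and 8 of 16 at the lower, on 3 against 3 and 3 against 2 arrays. A difference between sites stays open for the genes that kept their call under each scaling, among them CYP scc-24, Heme oxigenase32, Choriogenina L, GPX2 and XDh.

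Other splits of the same samples (100 each, the real one included) were counted. Chance could be excluded for the tissue differences, with 467 probes against at most 92 in another split. The same held for liver, ovary, gill and brain enrichment (104, 113, 64 and 42 probes, highest other 0 each). For the sites too the real split stood highest (115, highest other 45), and in each case 1 of 100 splits, the real one, gave as many. But the site count was 46 to 75 under the other scalings, where no splits were run. Chance is thus not excluded for the sites beyond the main processing. All splits used the main processing, where benzo(a)pyrene (10 probes, highest other 8) also stood alone among 100 splits. Its count was 0 with quantile normalization or median centring, so chance is not excluded for it beyond that processing. For cadmium (12 probes) 4 of 100 splits, the real one included, gave as many, a share only just under the 0.05 threshold. That share is not adjusted over the comparisons, and the highest other split gave 36, several times the real count. Chance is thus not excluded for the cadmium count, and the cause of such high counts was not tested. Where 0 probes were called, every split gives at least as many (100 of 100), so the count of splits says nothing about chance. This holds for male against female liver (highest other 1), acetone (0), nonylphenol (1) and nonylphenol against benzo(a)pyrene (51). The cause of the 51 was likewise not tested.

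The effect of intersex differed between gonad and liver for 252 probes in the interaction test. Among 239 groups of values, 10 held a sample far from the others, and chance flags about 1 in 20 groups. In female Ondarroa liver, TBTbp of replicate 3 was 5.76 (nearest other sample 6.70) and BAX of replicate 2 was −6.66 (−7.80). In female gonad, BAX of replicate 1 was −3.92 (−2.48), PMP70 of replicate 4 was 0.66 (−0.22) and VgC of replicate 3 was −4.67 (−5.30). In female brain the dopamine receptor of replicate 1 was −6.55 (−2.74). With cadmium, RXR of replicate 6 was −5.48 (−4.95). With benzo(a)pyrene, replicate 7 gave ERalpha at −4.80 (−6.44) and MT at 3.09 (4.31). With nonylphenol, CYP1A1 of replicate 2 was −0.33 (0.48).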

How the results depend on the processing

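The settings spot median, rRNA term and removal of dim arrays were chosen after the data were seen. Counts not given here stayed within 1.5 times the main count. The site comparison (115 probes) gave 50 with quantile normalization, 46 with median centring, 75 with scaling to probes measured on all arrays, 51 in the authors' table, 57 with slide as a block and 132 with the rRNA term. Cadmium (12) gave 2 with quantile normalization, 2 with median centring, 2 with scaling to measured probes, 2 with normexp, 2 in the authors' table, 2 against acetone, 4 with only its 2 groups in the fit and 4 without the dimmest arrays. Benzo(a)pyrene (10) gave 0 with quantile normalization, median centring, normexp, only its 2 groups or the seawater control, 5 with scaling to measured probes, 1 in the authors' table, 18 with the spot median, 21 without the dimmest arrays and 30 against the mean of both controls. Ovary gave 178 with median centring, gill 18 with scaling to measured probes and brain 22 with the strict filter, which tests fewer probes. Males gave 2 in a fit over all field arrays. Lists past the threshold (0), without the 2 added lists, were 1 with quantile normalization, 1 in the authors' table, 1 without the dimmest arrays, 46 with the preset correlation and 26 with fry. The preset correlation takes the probes of a list as near independent, though most genes carried several, so its count carries little weight. The cause of the other changes was not tested.

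In the gonads, values reversed for Trypsin (−0.54 quantile, −0.31 median centring, −0.54 authors' table), MVP (−1.38 median centring, −0.71 scaling to measured probes), Beta-Fibrinogen (−0.069 median centring), Calmodulin (−0.18, and −0.0067 in the interaction, median centring) and ABCC3 (−1.79 slide block); the cause was not tested. Of 4506 called values of named genes, 4168 kept their call, 332 lost it and the others reversed; MVP and ABCC3 were not called. Of values not called, 560 of 11301 changed sign.

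Leaving out 1 replicate gave, from lowest to highest, tissues 457 to 469, liver 101 to 108, ovary 105 to 120, gill 52 to 69, brain 38 to 44, sites 77 to 129, intersex liver 0 to 4, males 0 to 4, gonads 285 to 343, interaction 214 to 272, acetone 0 to 0, cadmium 2 to 50, benzo(a)pyrene 4 to 24, nonylphenol 0 to 4, nonylphenol against benzo(a)pyrene 0 to 0, and lists 0 to 1. A lone intersex sample was assumed to vary like the other groups.

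The replicate numbers were taken to pair liver, brain and gill, and also seawater and acetone, where a pairing is not shown. There the replicate block changed no call of a named gene or list (liver 102, gill 70, brain 45 and acetone 0 probes). Over all groups not every same-numbered pair correlated above 0.1: 27 of 33 of tissues, where the pairs with gonad fell short, 6 of 16 of livers, 17 of 43 of exposures and 0 of 2 of gonads, and 38 of 66 tissue comparisons matched best with their own number. With the replicate block benzo(a)pyrene gave 4, ABCC3 reversed to −2.34, and the other counts stayed within 1.5 times (sites 112, gonads 298, interaction 264, cadmium 13, tissues 469, ovary 116). Signal over background limits the dim genes, whose folds are bounds only where no array of a group measured them.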

Other observations

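The tests in this part were chosen after the pattern was seen in the same data. In female Ondarroa fish gonad, brain and gill carry sample numbers 1 to 6 and liver 1 to 5, and 33 of 483 probes (9 genes, 7 of them outside rRNA) differed between numbers across the tissues, against at most 4 in the other draws, and 1 of 100 draws, the real one, gave as many. MHC II, which presents antigens to T cells, was higher by 3.47 and 3.62 in numbers 2 and 3 than the mean of the numbers and lay between −2.16 and −1.71 in the others (adjusted p = 2.0e-04). The interferon-related genes VHSV-induced protein (2.05 in number 3, −2.21 in number 4) and MxP (2.38 and −2.09) also varied with the number. These genes, named here, were chosen after their values were seen. With a term for the rRNA split, which partly follows the numbers, 2 probes kept their call, both of MHC II (adjusted p = 0.00115). Numbers 1, 3, 4 and 5 each lay on a single slide in all their tissues, so slide and number cannot be told apart between them. Numbers 1 and 2 shared slide 1 in gonad, brain and gill, and MHC II differed between these 2 numbers. The labels do not say that equal numbers mark 1 fish.

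The rRNA signal of the 30 exposure arrays lay between 6.08 and 7.12, and none of them fell in the range of the 19 field arrays of lower signal.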
